A study of Mus musculus with 14 samples.

How the data were processed

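Messenger RNA was measured in liver sinusoidal endothelial cells (LSECs), the fenestrated cells that line the liver's capillaries. Per the labels' protocols, the cells were sorted by flow cytometry from female C57BL/6J wild-type mice with a gate for low CD45, high STAB2 and high CD146. RNA was extracted with TRIzol LS and libraries were made with the Ion AmpliSeq mouse transcriptome panel, which amplifies a short target in each gene instead of sampling whole transcripts. The 14 libraries comprise 7 from aged mice (10 to 11 months) and 7 from young mice (8 to 10 weeks). They were collected in 2 experiments, with 3 libraries per age in experiment 1 and 4 per age in experiment 2. Libraries are named by age and by the experiment and replicate number in the labels, so aged 1.3 is the aged replicate 3 of experiment 1. The labels do not say outright that each library comes from a separate mouse, so p-values measure the spread between these samples, which may be partly technical.

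The deposited values are raw, unnormalised read counts per RefSeq transcript, 1 file per library. Per the submitters' processing notes, the tools included HTSeq 0.6.0 and DESeq2 1.18.1. The aligner, the genome build, the strand setting and the treatment of reads shared between targets are not given in the sources used here. Each file held 23930 transcript targets and 5 bookkeeping entries of the counting tool. These entries held 1.24 to 3.04% of all reads and were left out of library sizes and tests. Gene names came from the RefSeq table of assembly GRCm38.p6 and, where that failed, from GENCODE release tables. In all, 18124 targets matched with their version, 4324 without it and 114 through GENCODE. The 1368 unmatched targets, which held 0.231 to 1.08% of gene reads, stayed in the tests under their identifiers. Genome coordinates are not given because the build behind the files is not stated.

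Gene reads per library ranged from 6710403 to 13977361. At this depth 12637 to 15168 targets had at least 10 reads, and the 20 most abundant targets took 11.7 to 15.1% of reads. Amplicon reads carry no molecular identifiers here, so a count is not a number of independent molecules.

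Counts were analysed in R 4.3.3 with edgeR 4.0.16. Targets were kept by filterByExpr, which left 14168, and libraries were scaled by the trimmed mean of M values (TMM). The quasi-likelihood F test compared aged with young with the experiment as a term. A model with 4 means, age by experiment, gave the contrast within each experiment and the difference between both contrasts. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. Fold changes are aged over young on the log2 scale, and each standard error (SE) was taken from the fold change and its F statistic. Levels are CPM, counts scaled to a common library size after TMM. Receptor reads, and values marked as such, were scaled without TMM. Agreement between the experiments was the Pearson and Spearman correlation of their log2 fold changes across genes, which are not independent replicates. Exact two-sided permutation tests of log2 CPM (prior count 2) permuted labels within experiments, and the smallest p they allow is 0.00143. Correlations across libraries were tested with 100000 permutations.

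The model, the tests, the gene lists and the rule for named genes were fixed before the data were examined. That rule took up to 12 genes per direction with the largest fold change among called genes with a mean of at least 5 CPM and the same direction in both experiments. It also took every gene on a study list drawn from the series title, up to 4 members with the smallest p from each list described, and up to 5 genes from the difference test. The 36 gene lists with at least 5 tested members were compared with all other genes by camera (limma 3.58.1) at a preset inter-gene correlation of 0.01. Each was tested again with an estimated correlation, with the rotation test fry and with an exact permutation of its mean log2 CPM. Camera p-values were adjusted over the 36 lists, and members were also adjusted over the list alone. The cholangiocyte list had too few tested members for a set test. The values of 1 gene are not reported here. The lists of other cell types cover cells that the sort could have let through.

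The steps were tested on simulated counts drawn from the real means and library sizes, with 50 genes changed at each fold size and 13806 genes tested. The combined comparison recovered 6 of 50 genes changed 1.5-fold, 18 at 2-fold, 36 at 4-fold and 40 at 8-fold, with 2 false calls among 13615 unchanged genes. Experiment 1 recovered 0, 7, 23 and 30 at these sizes, and experiment 2 recovered 0, 15, 25 and 33. The test of the difference between experiments made 0 calls on data in which none was simulated. Of 35 simulated lists, the list with raised genes was called, and 1 other was called as well. Genes were simulated independently of each other, unlike the real libraries, where members of a list are correlated. These numbers of false calls may therefore not hold for the real data.

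Replicates were compared before use. Aged 1.1 and aged 1.2 were the most alike, with a chi-square per degree of freedom of 6.35 against 19.6 to 124 for the other pairs within a group and experiment. They differed by more than counting noise and were kept as separate libraries, but whether they come from 1 pool is not known, in which case the aged n would be 6. Xist had 3678 to 10223 reads in each library and the 4 Y-linked genes checked had 0 or 1, as the label of female mice requires.

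Alternatives fixed in advance were DESeq2 size factors in edgeR, no TMM, no low-count filter, a stricter filter of at least 5 CPM in 7 libraries and a robust prior. They also included DESeq2 1.42.0, limma-voom, no experiment term, 1 surrogate variable (sva 3.50.0), the replicate number as a block, each experiment alone and leaving out each library in turn. Chosen after seeing the data were a term for reads on chemosensory receptor targets, leaving out young 2.2 and aged 2.4 together, a term for leukocyte markers, summing aged 1.1 with aged 1.2, and limma-voom with sample weights. The receptor term was the log2 CPM summed over the 1318 olfactory, vomeronasal and taste receptor targets. The leukocyte term was the mean log2 CPM of the 35 tested markers of Kupffer cells, monocytes and neutrophils, T and NK cells, and B and plasma cells.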

Results

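The transcriptome of sorted mouse LSECs was measured by targeted amplicon sequencing in 7 aged (10 to 11 months) and 7 young (8 to 10 weeks) libraries from female mice. Each library held 6710403 to 13977361 gene reads, and 14168 targets had enough reads to be tested. Of these, 1125 were olfactory, vomeronasal or taste receptor targets, which are counted among the 14168 genes in the numbers below. The series title concerns iron-triggered signalling through the p38 kinase and the transcription factor ETS1 in LSECs, independent of NRF2, and its effect on Bmp6. Bmp6 encodes a bone morphogenetic protein that LSECs release to induce hepcidin, the hormone that limits iron uptake. The age comparison asks which LSEC transcripts differ between aged and young mice. The LSEC scavenger receptor gene Stab2 lay between 1890 and 2210 CPM in every library when scaled without TMM. With TMM it averaged 1984 ± 164.4 CPM in aged and 2109 ± 245.8 CPM in young libraries (SD).

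Libraries differed in reads on targets that are not LSEC genes. Reads on olfactory, vomeronasal and taste receptor targets, genes silent in liver endothelium, made up 1.19 to 3.15% of gene reads in experiment 1 and 0.145 to 2.90% in experiment 2. In experiment 2, young 2.2 at 2.90% and aged 2.4 at 2.78% stood above the other 6 libraries, which reached at most 0.953%. On the log2 scale these shares differed between aged and young by a mean of −0.13 against an SD of 1.37 within groups (exact permutation p = 0.833). They followed the first principal component of all other tested targets, which held 59.2% of the variance. Only receptor targets were left out of that component, so single-exon targets of other families stayed in. Over the 14 libraries Pearson's r was −0.994 (permutation p = 1e-05, the smallest the permutations can give) and Spearman's rho was −0.921 (permutation p = 2e-05). Pearson's r was −0.992 without the 2 farthest libraries, −0.957 within experiment 1 and −0.993 within experiment 2. It was 1 of 4 such relations computed, with Benjamini-Hochberg adjusted p-values of 1.33e-05 for Pearson's r and 2.67e-05 for Spearman's rho.

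**Figure D1:**
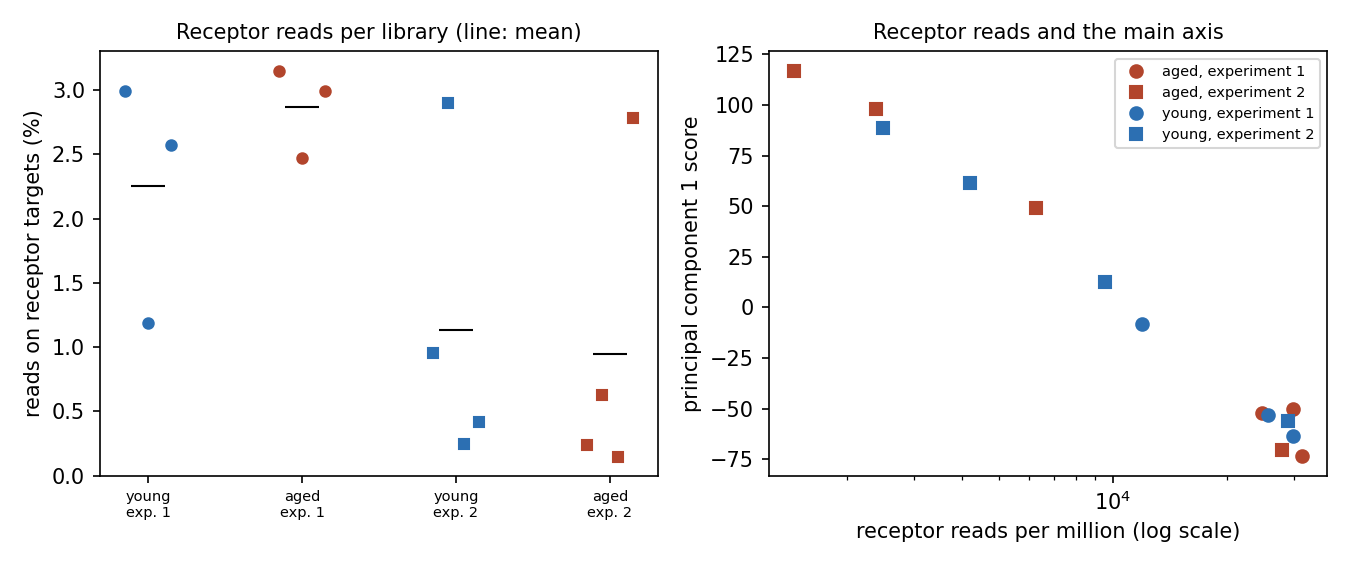
Left, percentage of gene reads on olfactory, vomeronasal and taste receptor targets in each library, by age and experiment, with a line at each mean. Right, receptor reads in CPM without TMM scaling (log axis) against the score on principal component 1. The component was computed without receptor targets, and the 14 libraries fall along a line (r = −0.994).

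In aged LSECs 11 genes rose and 12 fell out of 14168 tested. Genes for 2 chains of basement membrane collagen were among the strongest rises. Col4a4 (NM_007735.2) rose 7.03-fold, from 2.11 ± 1.27 to 13.4 ± 3.41 CPM (SD, n = 7 libraries per age; log2 fold change 2.81, SE 0.251, adjusted p = 0.000336). Its partner Col4a3 rose 4.53-fold (adjusted p = 0.0325). Ptgis (NM_008968.3), which encodes prostacyclin synthase, the enzyme that makes the vasodilator prostacyclin, rose 6.73-fold from 2.04 ± 1.32 to 14.9 ± 8.37 CPM (adjusted p = 0.033). Dkk3 (NM_015814.2), a secreted glycoprotein of the Dickkopf family and a marker of LSECs near the central vein, rose 3.45-fold from 21.1 ± 11.7 to 70.6 ± 23.2 CPM (adjusted p = 0.00714). The membrane protein gene Tmem63c (NM_172583.2) rose 7.82-fold, from 1.05 ± 0.445 to 9.01 ± 5.26 CPM (adjusted p = 0.00714). Ccbe1, needed for the processing of the lymphatic growth factor VEGF-C, rose 4.17-fold, and the calcium channel adaptor gene Stac2 rose 6.82-fold. Cyp4v3, a fatty acid hydroxylase, AU021092 and the fucosidase Fuca2 rose 2.28-fold, 2.07-fold and 1.88-fold. On the log2 scale each of these 10 genes was above the young mean of its experiment in 7 of 7 aged libraries, although for Col4a3 aged 1.3, at 4.85 CPM, lay under the mean of 4.94 CPM of the young libraries of its experiment. Selection of the genes in these same libraries favours such a count.

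Among the 12 genes that fell, Smtn (NM_001159284.1), which encodes the actin-binding protein smoothelin, fell from 154.8 ± 28.4 to 97.3 ± 17.8 CPM, 1.60-fold (SD, n = 7 libraries per age; adjusted p = 0.0175). Rdx (NM_001104616.1), for radixin, which ties actin to the plasma membrane, fell 2.10-fold from 182.4 ± 56.2 to 86.9 ± 30.7 CPM (adjusted p = 0.0442). Plcb1, a phospholipase C that acts downstream of G protein-coupled receptors, fell 2.55-fold, and the phospholipid flippase Atp9a fell 2.52-fold. The interferon-induced genes Ifi44 (NM_133871.2) and Ifi213 fell 1.97-fold and 2.02-fold, Ifi44 from 146.2 ± 26.5 to 74.0 ± 16.7 CPM (adjusted p = 0.0357). Clca3a1, of a family of chloride channel regulators, fell 3.12-fold and Reep1, which shapes the endoplasmic reticulum, 1.84-fold. All 8 were below the young mean of their experiment in 7 of 7 aged libraries, which their selection in these same libraries favours. Clca3a1 and Ifi213 belong to families of near-identical paralogs, so their counts are uncertain. A further 5 called genes averaged under 5 CPM and are named here after their values were seen: Slc41a2 rose by a log2 fold change of 1.81, while Mettl24 (−4.21), Lrch2 (−2.92), Mdga1 (−2.73) and Cfap69 (−2.49) fell.

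**Figure D2:**
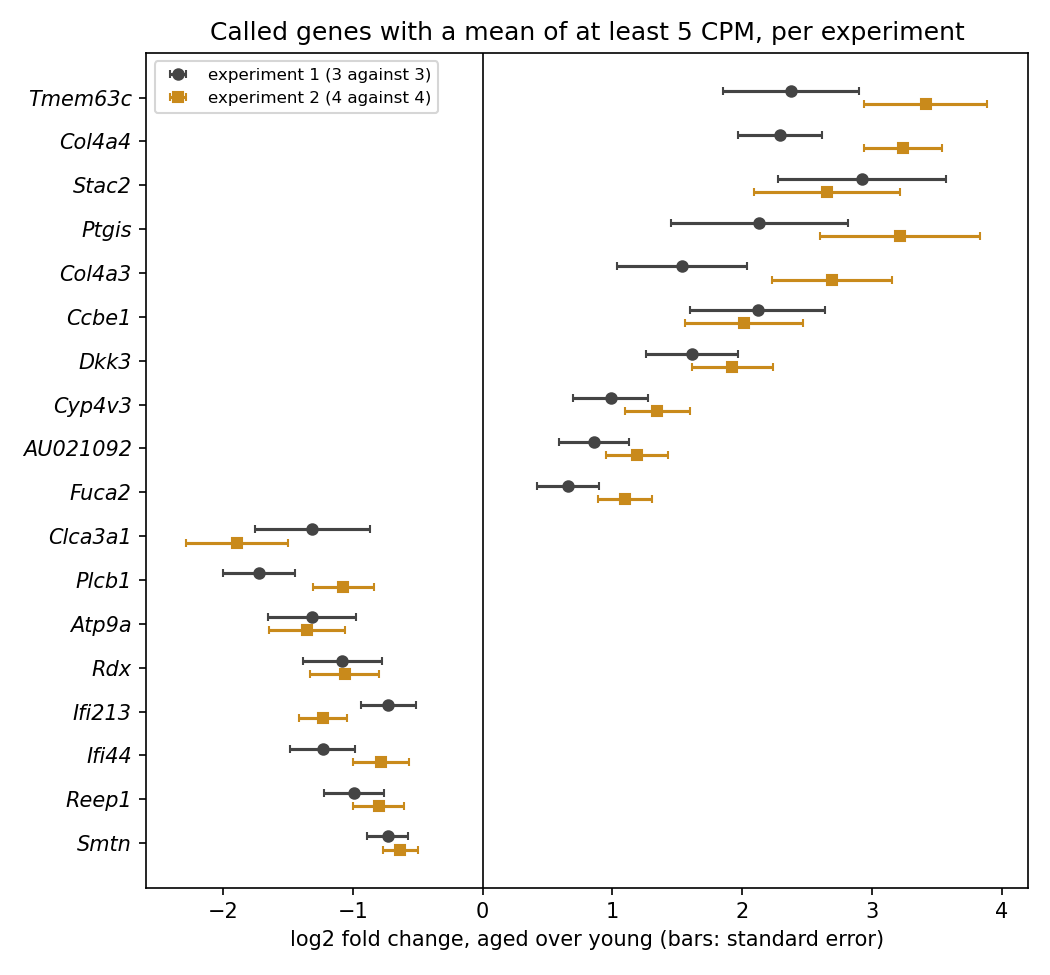
Log2 fold change, aged over young, of the 18 called genes with a mean of at least 5 CPM, estimated separately in experiment 1 (3 against 3 libraries) and experiment 2 (4 against 4 libraries). The 18 were chosen to have the same direction in both experiments, and the plot shows the size in each, for example Dkk3 at 1.61 and 1.92 and Rdx at −1.08 and −1.06.

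The 23 calls came from edgeR's quasi-likelihood test over both experiments, in which 959 genes had an unadjusted p under 0.05 where chance gives 708. Leaving out 1 library could lower that number. It was 4 without aged 1.1, 4 without aged 1.2, 5 without aged 2.1, 5 without young 2.4, 8 without aged 2.2, 9 without young 1.3, 9 without aged 2.3, 10 without young 1.1 and 11 without young 2.3. Tmem63c, Col4a4, Dkk3 and Cfap69 were called in all 14 runs that left out 1 library. Of the other named genes, Plcb1 was called in 11 runs, Stac2 and Smtn in 10, Atp9a and Ifi213 in 7, Ccbe1 in 6, Cyp4v3 in 5, Col4a3, AU021092 and Fuca2 in 4, Ptgis in 3, Ifi44 and Reep1 in 2, and Clca3a1 and Rdx in 1. Aged 1.1 and aged 1.2 were more alike than any other pair, and whether they are separate mice is not known. Summed as 1 library, which leaves 6 aged libraries, they gave 4 calls, Tmem63c, Col4a4, Dkk3 and Cfap69. With no TMM scaling 28 genes rose and 18 fell. A term for receptor reads gave 59 calls including all 23, and leaving out young 2.2 and aged 2.4 gave 36. The replicate number as a block gave 5 calls, 4 of them among the 23. With a term for leukocyte markers 3 calls were left, Tmem63c, Col4a4 and Ccbe1, with log2 fold changes of 3.06, 2.82 and 2.47. The 20 other genes had 0.84 to 1.13 times their log2 fold change without the term and an SE 1.04 to 1.29 times as large, so these calls ended with larger errors and with folds close to those before. Dkk3 went from 1.79 (SE 0.23) to 1.70 (SE 0.263, adjusted p = 0.0646) and Ptgis from 2.75 (SE 0.469) to 3.10 (SE 0.558, adjusted p = 0.128).

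Bmp6 (NM_007556.3), the gene in the series title, was 1.60-fold higher in aged LSECs (95% interval 1.20 to 2.12), at 574.8 ± 101.5 against 359.7 ± 120.9 CPM (SD, n = 7 libraries per age). It was above the young mean in 7 of 7 aged libraries, with log2 fold changes of 0.691 in experiment 1 and 0.662 in experiment 2. Slc40a1 (NM_016917.2), which encodes the iron exporter ferroportin, was at 306.9 ± 78.6 against 209.7 ± 45.7 CPM, 1.46-fold (95% interval 1.09 to 1.96), higher in 6 of 7. Ets1 was at 952.6 ± 258.2 CPM in aged and 1161 ± 259.8 CPM in young LSECs, and the heme oxygenase gene Hmox1 at 120.2 ± 20.5 and 99.7 ± 21.1 CPM. Nfe2l2, which encodes NRF2, and Mapk14, which encodes p38 alpha, had log2 fold changes of 0.104 (SE 0.146) and −0.037 (SE 0.178). Those of Bmp2, Nqo1, Tfrc, Id1, Smad6 and Smad7 were 0.067, 0.235, 0.154, 0.028, 0.122 and 0.061. The sign for Mapk14 turned with no TMM scaling, to 0.008.

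Over all 14168 genes none of the 12 tested study genes passed, Bmp6 having an adjusted p of 0.41. The count was 1 when adjusted over the list alone, Bmp6 at 0.0327, while Slc40a1 was at 0.0748, Ets1 at 0.273 and Hmox1 at 0.273. An exact permutation within experiments gave p = 0.00429 for Bmp6, which is 0.0514 adjusted over the list, and 0.0357 for Slc40a1. The list was drawn from the series title, so its count is not independent of what the study reported. Adjusted over the list alone, Bmp6 stayed under 0.05 in 5 of 14 runs that left out 1 library. It missed that threshold without aged 1.1 (0.0748), aged 1.2 (0.0841), aged 2.1 (0.0585), aged 2.2 (0.0565), aged 2.3 (0.0667), aged 2.4 (0.0532), young 1.1 (0.0852), young 1.3 (0.0693) and young 2.4 (0.073). The list's count was 2 without young 1.2 or aged 1.3, where Slc40a1 passed (0.049 and 0.0128), and without young 2.2, where Ets1 did (0.0338). Bmp6 also missed the threshold with no experiment term (0.0546) and with aged 1.1 and aged 1.2 summed (0.0797). With the receptor term Bmp6, Slc40a1 and Ets1 were at 0.012, 0.0209 and 0.0209, which passes for all 3. Of 14 listed genes Fth1 had 0 or 1 read per library and Ftl1 was not matched to a target, so the ferritin subunits are not reported.

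**Figure D3:**
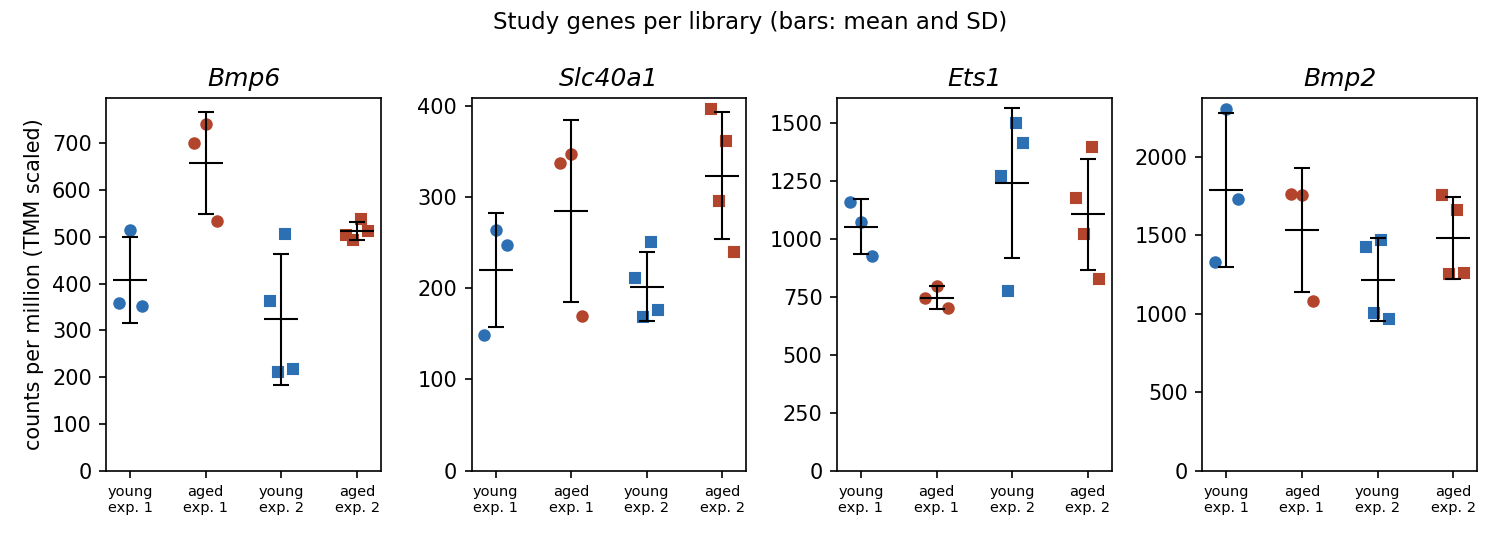
Expression in CPM of Bmp6, Slc40a1, Ets1 and Bmp2 in each library, by age and experiment, with bars at the mean and SD (n = 3 per age in experiment 1, n = 4 per age in experiment 2). Bmp6 averaged 658.6 and 512.0 CPM in the aged groups and 407.8 and 323.7 CPM in the young groups of experiments 1 and 2.

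Within the experiments the age comparison asks whether either alone shows the difference. In experiment 2 Col4a4 rose, with a log2 fold change of 3.24 (SE 0.299, adjusted p = 0.00113), and in experiment 1 its value was 2.29 (SE 0.325, adjusted p = 0.131). Tmem63c had values of 2.38 and 3.42 in experiments 1 and 2. In experiment 1 edgeR called 0 genes, with 914 at an unadjusted p under 0.05 where chance gives 708, while DESeq2 called 74 and limma-voom 1. In experiment 2 edgeR called Col4a4 alone, with 395 genes at an unadjusted p under 0.05, fewer than the 708 of chance, while DESeq2 called 48 and limma-voom 3. The count in experiment 2 was 3 without aged 2.4 and 2 without young 1.1, young 1.2, aged 1.3, young 2.1, young 2.2 or aged 2.3. No gene was called in experiment 2 when it was fitted alone or with the replicate number as a block.

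The test of a different age effect in the 2 experiments called 0 genes by edgeR, with 309 at an unadjusted p under 0.05 against 708 by chance, 0 by limma-voom and 1 by DESeq2. All 23 genes called over both experiments had the same direction in each, which their selection by the combined test favours. Across all 14168 genes the log2 fold changes of both experiments had a Pearson r of 0.341 and a Spearman rho of 0.131. Of 914 genes with an unadjusted p under 0.05 in experiment 1, 73.2% had the same sign in experiment 2, and of 395 such genes in experiment 2, 78.7% had it in experiment 1, against 52.2% of all genes. Without young 2.2 and aged 2.4 the Pearson r was 0.264 and the Spearman rho −0.052.

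Of 36 gene lists 15 passed camera at the preset correlation, 9 higher and 6 lower in aged LSECs. None passed with an estimated correlation, by directional fry or by exact permutation of the list score after adjustment, and 6 passed fry's test for change in either direction, which does not compare a list with other genes. Those were KLF2 and nitric oxide (adjusted p = 0.00059), type I interferon response (0.000905), pericentral LSEC (0.00209), extracellular matrix (0.0301), and continuous capillary endothelium and Kupffer cell markers (0.04 each). When libraries were regrouped at random within experiments, 39 of 100 splits, the real one included, put at least 15 lists past the camera threshold. Each list that passed is therefore given with its adjusted p from the estimated correlation and its members' own counts. With the receptor term the number of members past the threshold over the list alone went from 0 to 10 for early response, 3 to 8 for matrix, 6 to 9 for interferon, 2 to 5 for NRF2, 7 to 10 for MHC class II and for Kupffer, 2 to 4 for KLF2 and nitric oxide, and 0 to 2 for ETS genes. It went from 2 to 0 for inflammation, and from 0 to 1 for iron handling and for the circadian clock, while for LSEC identity 2 rose and 3 fell in place of 0. For capillary genes it went from 3 to 4, for B and plasma cell markers from 5 to 6, and for the unfolded protein and integrated stress response from 0 to 2. Over all genes it went from 1 to 2 for interferon and for KLF2 and nitric oxide. It went from 0 to 1 for early response, matrix, capillary, and unfolded protein and integrated stress response genes.

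Markers of Kupffer cells and macrophages, the resident phagocytes of the sinusoid, were higher in aged libraries for 11 of 11 tested genes, with a median log2 fold change of 1.66. None passed over all genes, and 7 rose when adjusted over the list alone, among them the folate receptor Folr2 (11.8 ± 10.3 against 3.46 ± 3.33 CPM, SD, n = 7), Cd163 (5.58 ± 3.34 against 1.20 ± 1.36 CPM), Vsig4 (27.5 ± 16.4 against 7.70 ± 5.44 CPM) and the Kupffer cell lectin Clec4f (26.2 ± 19.7 against 8.38 ± 7.67 CPM). The camera adjusted p was 7.08e-15, with an adjusted p = 0.147 with an estimated correlation, and the list score gave an exact permutation p of 0.0114 (0.206 adjusted). Without aged 1.3, 0 of these genes passed over the list alone. The count was 4 without young 1.1, young 1.2, aged 2.1, young 2.2, aged 2.2 or young 2.3.

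Genes of MHC class II presentation, by which cells show antigen to helper T cells, had a median log2 fold change of 1.94. None passed over all genes, and 7 of 12 rose when adjusted over the list alone, led by the lysosomal reductase Ifi30, H2-DMb1, the invariant chain Cd74 and Cd86. Cd74 averaged 577.5 ± 605.4 CPM in aged and 162.3 ± 195.0 CPM in young libraries. Scaled without TMM, Cd74 ranged from 30.6 CPM in aged 2.4 to 1460 CPM in aged 2.2. The camera adjusted p was 1.67e-09, with an adjusted p = 0.26 with an estimated correlation. None of the 7 passed without young 1.1, young 1.2, aged 1.3, young 1.3, aged 2.1, young 2.2, aged 2.2, young 2.3 or young 2.4. With the leukocyte term the list's median was 0.11 and it no longer passed (adjusted p = 0.368).

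B and plasma cell markers had a median of 3.07, and 0 passed over all genes while 5 of 7 rose when adjusted over the list alone, with Cd22 at 15.2 ± 18.4 against 2.24 ± 3.35 CPM and Cd79b at 32.8 ± 40.9 against 4.88 ± 7.50 CPM (adjusted p = 0.325 with an estimated correlation). None of the 5 passed without young 1.1, young 1.2, aged 1.3, young 1.3, aged 2.1, aged 2.2, young 2.3 or young 2.4. The 5 monocyte and neutrophil markers had a median of 1.83, with 0 passing over all genes or adjusted over the list alone (adjusted p = 0.26 with an estimated correlation). Adjusted over the list alone, 4 passed without aged 1.1, 3 without young 2.2 and 6 without aged 2.4, where more markers were tested. Of 5 tested dendritic cell markers 2 reached 5 CPM in every library, and which cells their reads came from was not tested. Among these 5 markers 0 passed over all genes, and Clec9a (214.0 ± 54.6 against 123.8 ± 34.2 CPM) and Ly6d rose when adjusted over the list alone (median 0.516, adjusted p = 0.216 with an estimated correlation). The count was 1 without young 1.2, aged 1.3, young 1.3, aged 2.1, aged 2.2, young 2.3 or young 2.4. T and NK cell markers had a median of 0.807, made of 4.32 in experiment 1 and −0.735 in experiment 2, and hepatocyte markers 0.771, made of 1.96 and −0.116. No member of either list passed over all genes or adjusted over the list alone, and the adjusted p with an estimated correlation was 0.635 for each. Aged 1.3 had 3700 CPM of the hepatocyte gene Alb, scaled without TMM. With this library left out the medians were −0.213 for T and NK cells (camera adjusted p = 0.811) and −0.284 for hepatocytes. The hepatocyte list was then past the threshold in the lower direction (0.0465). The hepatocyte list did not pass without young 1.3 (0.0744) or young 2.4 (0.0835). The T and NK cell list did not pass without young 1.1 (0.0829), young 1.2 (0.129), young 1.3 (0.0901), aged 2.1 (0.101), aged 2.2 (0.0631), young 2.3 (0.0986) or young 2.4 (0.211). With the leukocyte term the dendritic cell list, none of whose members is in the term, no longer passed (adjusted p = 0.0871). The term is built from the Kupffer, monocyte and neutrophil, T and NK, and B and plasma cell markers, so it cannot test those lists.

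Genes of the type I interferon response were lower in aged LSECs for 17 of 18 tested members, with a median log2 fold change of −0.301 (camera adjusted p = 1.92e-12; adjusted p = 0.147 with an estimated correlation). Of the 18, Ifi44 alone fell over all genes, and 6 fell when adjusted over the list alone, including the RNA sensor Oas1a (21.7 ± 4.56 against 34.1 ± 6.60 CPM, SD, n = 7), the translation inhibitor Ifit1 (39.0 ± 6.83 against 64.2 ± 22.1 CPM) and Oasl2 (189.9 ± 27.7 against 258.2 ± 58.7 CPM). Directional fry gave an adjusted p of 0.1, and the list score an exact permutation p of 0.00571 (0.206 adjusted). Leaving out 1 library gave 5 to 9 such members, the highest, 9, without young 1.1 or young 2.1. The list stayed past the threshold with the leukocyte term (median −0.244). MHC class I presentation genes, which interferon also induces, had a median of −0.003, and 0 of 13 passed over all genes or adjusted over the list alone.

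Immediate early and heat shock genes, which cells switch on within minutes of handling or stress, were lower in aged libraries for 19 of 20 genes, with a median log2 fold change of −0.794. None passed over all genes or adjusted over the list alone, while with the receptor term 1 and 10 did. Examples are Atf3 at 43.8 ± 32.1 against 240.7 ± 214.9 CPM and Zfp36 at 1078 ± 323.5 against 2156 ± 1135 CPM (SD, n = 7). The camera adjusted p was 2.31e-11, with an adjusted p = 0.26 with an estimated correlation, and the exact permutation p of the score was 0.127. With the leukocyte term the median was −0.424 (camera adjusted p = 0.00127). Without young 2.2, 16 members passed when adjusted over the list alone, and without young 2.1, 1 did. Inflammation and NF-kB genes did not pass camera (adjusted p = 0.112), and 0 passed over all genes, but the neutrophil chemokine Cxcl1 (18.8 ± 14.5 against 66.0 ± 56.5 CPM) and the interferon-induced chemokine Cxcl10 (233.2 ± 97.8 against 584.7 ± 421.2 CPM) fell when adjusted over the list alone. With the receptor term neither did. Senescence genes did not pass camera (adjusted p = 0.141), and their 1 member to change over the list alone, the cell cycle inhibitor Cdkn1a, fell from 119.8 ± 49.1 to 70.4 ± 7.52 CPM, with 0 passing over all genes.

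Targets of NRF2, the regulator of antioxidant genes, were higher in aged LSECs for 20 of 21 genes, with a median log2 fold change of 0.242. None passed over all genes, and Aox1 (12.3 ± 2.79 against 6.17 ± 2.50 CPM, SD, n = 7) and the glutathione transferase Gstm1 (161.2 ± 40.4 against 114.0 ± 22.4 CPM) rose when adjusted over the list alone. Gclc, the catalytic subunit of the enzyme that limits glutathione synthesis, was at 108.5 ± 21.7 against 86.1 ± 14.3 CPM. The camera adjusted p was 3.86e-08, with an adjusted p = 0.252 with an estimated correlation. Neither member passed without aged 1.1, young 1.1, aged 1.2, aged 1.3, young 1.3, aged 2.1, young 2.2, aged 2.3 or young 2.4, while 3 passed without young 1.2, young 2.1 or young 2.3 and 4 without aged 2.4.

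Iron and heme handling genes (median 0.057, camera adjusted p = 0.0675) did not pass camera, and 0 of 29 passed over all genes or adjusted over the list alone. Its smallest p-values belonged to the hemoglobin scavenger receptor Cd163 and the heme-hemopexin receptor Lrp1, with log2 fold changes of 2.34 and 1.28. Cd163 is also among the Kupffer cell and macrophage markers, which were higher in aged libraries. Genes of BMP ligands, receptors and SMADs (median 0.054, camera adjusted p = 0.19) and angiocrine factors (0.148, 0.113) did not pass either. No member of these passed over all genes, and in each Bmp6 alone rose when adjusted over the list alone. Targets of BMP SMAD signalling had a median of 0.103 with 0 of 12 passing over all genes or adjusted over the list alone, the BMP pseudoreceptor Bambi being at 32.3 ± 9.73 against 52.7 ± 17.9 CPM. Among p38 pathway genes (median −0.052) 0 passed over all genes, and the kinase Map3k5 rose when adjusted over the list alone, from 0.661 ± 0.623 to 2.61 ± 1.41 CPM. Among ETS factors (median −0.075) 0 of 15 passed over all genes or adjusted over the list alone, Ets2 being at 215.0 ± 52.2 against 295.0 ± 73.0 CPM.

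Extracellular matrix genes were lower in aged LSECs for 17 of 27 tested members and higher for 10, with a median log2 fold change of −0.238 (adjusted p = 0.354 with an estimated correlation; exact permutation p of the score 0.181). Genes of continuous capillary endothelium were lower for 19 of 23, with a median of −0.265 (adjusted p = 0.325 with an estimated correlation; exact permutation p of the score 0.473). Without young 2.4 these medians were −0.069 and −0.085 (camera adjusted p = 0.0169 and 0.0479), and that library had a capillary score of 6.42 mean log2 CPM against 5.01 to 5.61 in the other young libraries. None of their members passed over all genes. Adjusted over the list alone, the basement membrane collagens Col4a1 (827.7 ± 191.6 against 1348 ± 457.4 CPM, SD, n = 7) and Col4a2 (237.4 ± 60.0 against 366.2 ± 90.3 CPM) fell in both lists, the matrix glycoprotein Sparc in the first and the diaphragm protein gene Plvap (607.4 ± 139.6 against 947.6 ± 367.1 CPM) in the second. This is the opposite direction to Col4a3 and Col4a4, which are expressed at a far lower level. Of matrix genes 0 passed over the list alone without aged 2.2, 1 without aged 1.1, young 1.1, aged 1.2, young 1.2, young 2.4 or aged 2.4, 5 without young 2.1 and 9 without young 2.2. Of capillary genes 1 passed without aged 1.1, young 1.1, aged 1.2, young 1.2, aged 2.2, young 2.3, young 2.4 or aged 2.4, and 5 without aged 1.3. With the leukocyte term the matrix median was −0.136 (camera adjusted p = 0.033). The capillary median was −0.195 with that term, and the list no longer passed (camera adjusted p = 0.0871).

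LSEC identity genes were lower for 24 of 32 members with a median of −0.144, and 0 passed over all genes or adjusted over the list alone (adjusted p = 0.647 with an estimated correlation). The largest list member differences by p were in the soluble lectin Fcna (9.72 ± 4.36 against 4.28 ± 1.42 CPM), Clec1b, Tfec and Dab2. The list no longer passed without young 1.2 (0.379), aged 1.3 (0.6), young 2.3 (0.192) or aged 2.4 (0.262), nor with the leukocyte term (0.643). Adjusted over the list alone, 1 member passed without aged 1.1 or aged 1.2 and 2 without aged 1.3 or young 2.2. Pericentral (median −0.32, camera adjusted p = 0.306) and periportal (0.072, 0.383) LSEC genes did not pass camera, while the pericentral list passed fry's test for change in either direction. Among pericentral genes Dkk3 rose, over all genes and adjusted over the list alone, and no periportal gene passed either adjustment. KLF2 and nitric oxide genes (median −0.242, camera adjusted p = 0.131) passed that fry test but not camera. Of them Ptgis rose over all genes and adjusted over the list alone, and the guanylate cyclase subunit Gucy1b1 fell when adjusted over the list alone, from 11.1 ± 6.69 to 5.79 ± 4.69 CPM. Klf2, the shear-induced transcription factor, was at 918.7 ± 388.1 against 1601 ± 506.0 CPM and did not pass over the list alone (adjusted p = 0.136), but passed over all genes with the receptor term (adjusted p = 0.019). No member passed either adjustment in the lists for scavenging and endocytosis (median −0.032), Notch signalling (0.047) or arterial, venous and lymphatic endothelium (0.093), and none of these lists passed camera or fry.

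Cell cycle genes were lower in aged libraries for 24 of 27 members with a median of −0.56, and 0 passed over all genes or adjusted over the list alone (adjusted p = 0.635 with an estimated correlation). Cdk1 was at 20.9 ± 7.46 against 44.2 ± 42.4 CPM. Without young 2.4 the median was −0.058 and the list did not pass (adjusted p = 0.354), nor did it with the leukocyte term (0.823). Adjusted over the list alone, 2 members passed without young 2.1. Ribosomal protein genes, of which the panel measured 15 of 69, were higher with a median of 0.211, and 0 of 12 passed over all genes or adjusted over the list alone (adjusted p = 0.434 with an estimated correlation; 0.0537 with the leukocyte term). Lists for oxidative phosphorylation (median −0.005), cholesterol synthesis (−0.002), stellate cells and fibroblasts (0.179) and erythroid cells and platelets (0.331) did not pass camera, and 0 of their members passed over all genes or adjusted over the list alone.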

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

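In 9 of 104 groups of 7 libraries, the highest or lowest library stood apart from the rest, where chance alone gives about 5.2. The measure was the gap to the nearest other library as a share of the group's range, and no test in this part was chosen after the values were seen. Stac2 stood apart in aged 2.4 (ratio 0.598), at 1.59 log2 CPM against 2.90 to 3.78 in the other aged libraries. AU021092 did so in aged 2.4 (0.578), at 6.40 against 7.04 to 7.51. Mapk14 also did so in aged 2.4 (0.603), at 6.23 against 7.12 to 7.70. Ifi44 was lowest in aged 1.3 (0.694), at 5.30 against 6.09 to 6.44. Mettl24 was lowest in young 1.3 (0.668), at 0.52 against 1.84 to 2.50 in the other young libraries. Among list scores, in mean log2 CPM, continuous capillary endothelium was high in young 2.4 (0.573), at 6.42 against 5.01 to 5.61. The cell cycle score was high in aged 2.4 (0.624), at 4.85 against 3.11 to 3.76. The hepatocyte marker score was high in aged 1.3 (0.617), at 7.47 against 3.54 to 5.05. The dendritic cell score was low in aged 2.3 (0.602), at 3.77 against 4.88 to 5.61. No explanation of these values was tested, except for aged 1.3 as the sole source of the higher leukocyte markers.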

How the results depend on the processing

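The alternatives with a receptor term, a leukocyte term, 2 libraries out, 2 libraries summed or sample weights were chosen after seeing the data. None of the 23 called genes changed direction. Of 322 values with 1 library left out, 155 were still called, as were 258 of 338 under the other alternatives. Where a call or direction changed, the cause was not tested, except that runs with fewer libraries have less information. In data simulated with these library sizes and this number of libraries, 18 of 50 genes changed 2-fold were recovered, and the share owed to depth was not tested.

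The count of genes changed between aged and young, 23, became 46 with total count scaling only, 12 with no experiment term, 58 with 1 surrogate variable, 143 with DESeq2, 59 with the receptor term, 36 with young 2.2 and aged 2.4 out, 3 with the leukocyte term, 4 with aged 1.1 and 1.2 summed and 369 with limma-voom with sample weights. Leaving out 1 library gave 4 to 29. With total count scaling 28 rose and 18 fell, against 11 and 12 with TMM. In experiment 1 the count of 0 became 1 with limma-voom, 74 with DESeq2 and 2 with the receptor term. In experiment 2 the count of 1 became 3 with DESeq2 size factors, 2 with the stricter filter, 3 with limma-voom, 48 with DESeq2, 0 when fitted alone, 21 with the receptor term and 3 with 2 libraries out, and 1 to 3 with 1 library left out. The difference between experiments gave 1 gene with DESeq2 in place of 0.

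Of the study genes 1 passed over the list alone, against 2 with total count scaling, 2 with the stricter filter, 0 with no experiment term, 3 with 1 surrogate variable, 3 with the receptor term, 2 with 2 libraries out, 0 with aged 1.1 and 1.2 summed and 3 with sample weights. Leaving out 1 library gave 0 to 2. Bmp6 passed over all genes only with sample weights, at a log2 fold change of 0.847 (adjusted p = 0.00626, where all alternatives span 0.00626 to 0.793). Slc40a1 passed over all genes with sample weights as well, at 0.619 (adjusted p = 0.0256). Genes near 0 changed sign. Mapk14 was at 0.008 with total count scaling, 0.066 with 2 libraries out and −0.103 to 0.092 with 1 left out. Tfrc was at −0.153 with limma-voom, −0.817 with the leukocyte term, −0.58 with sample weights and −0.633 to 0.384 with 1 library left out. Id1 was at −0.021 with the sum and −0.083 to 0.149 with 1 left out, Bmp2 at −0.006 to 0.177 and Smad7 at −0.009 to 0.181.

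Of the gene lists 15 passed, against 0 with camera at an estimated correlation and 0 with fry, and 13 to 20 under the others. Hepatocyte markers had a median of −0.141 with the leukocyte term and −0.284 to 0.975 with 1 library left out, and T and NK cell markers, which are part of that term, −1.688 with it. The agreement of the experiments, r = 0.341, was 0.36 for genes of at least 5 CPM, 0.418 with the receptor term and 0.264 with 2 libraries out.

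With the replicate number as a block, 5 genes were called between aged and young, 4 of them among the 23, and 0 in experiment 2, and Tfrc was at −0.124. Same-numbered aged and young libraries correlated at −0.38 to 0.78, and the own number was highest for 3 of 7. With 3 or 4 candidate libraries for each, this count can neither show nor exclude a pairing.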

Other observations

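The receptor, leukocyte and sample weight alternatives were chosen after the results were seen, as were the tests of receptor reads against age and against the main axis, of list scores without aged 1.3, and all counts of other splits except those for gene lists and for agreement. With the receptor term 59 genes were called, 28 higher and 31 lower in aged LSECs, and the following were picked from them after their values were seen. Pltp, the plasma phospholipid transfer protein, had a log2 fold change of 1.12 (SE 0.192) and the complement gene C2 one of 1.39 (SE 0.185). The junction gene Jam3 was at 0.604 (SE 0.109). Lower in aged LSECs were Stc1, a secreted glycoprotein, at −2.98 (SE 0.521), the elastic fibre protein gene Emilin1 at −0.619 (SE 0.105), the endothelial adhesion gene Icam2 at −0.484 (SE 0.089) and Klf2 at −0.97 (SE 0.171). Without the term none of these 7 passed over all genes, their adjusted p-values lying between 0.0523 for Stc1 and 0.676 for Klf2.

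Circadian clock genes did not pass as a list (median log2 fold change 0.223, camera adjusted p = 0.134), and 0 of 16 passed over all genes or adjusted over the list alone. With the receptor term 1 of them rose when adjusted over the list alone. The clock output factor Hlf was at 3.76 ± 1.51 CPM in aged and 0.939 ± 0.864 CPM in young libraries, and the clock repressor Nr1d1 at 88.9 ± 30.7 and 48.2 ± 25.3 CPM (SD, n = 7). The unfolded protein and integrated stress response list did not pass (median −0.15, camera adjusted p = 0.112), with 0 of 19 past either adjustment; with the receptor term the list passed (camera adjusted p = 0.0369) and 2 members fell over the list alone. Its transcription factor Atf4 was at 489.3 ± 146.5 against 683.6 ± 169.6 CPM and passed over all genes with the receptor term only (adjusted p = 0.0477). Among cholangiocyte markers, too few for a set test, Krt19 had 18 to 234 reads per library with a log2 fold change of 0.235, and Epcam had 3 to 322 reads with one of 1.42.

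Reads on chemosensory receptor targets may come from genomic DNA amplified with the cDNA. In the 7 libraries with the most receptor reads, 417 silent single-exon targets outside these families had a median of 17.7 CPM against 0.126 CPM for 8220 silent multi-exon targets, a ratio of 140, and the 1 silent Y-linked single-exon target had 0. Age is argued against as the main source of the variation, since the difference of −0.13 on the log2 scale lay under the SD of 1.37 within groups. The test found no age difference (exact permutation p = 0.833), but with this spread it cannot exclude one. By experiment, the mean in aged libraries was higher by 0.45 in experiment 1 and lower by 0.57 in experiment 2. Receptor reads tracked principal component 1 (r = −0.994), and they did so as well for the component of 6302 expressed multi-exon targets, where r was −0.969 and rho −0.93 (permutation p = 1e-05, the smallest possible, and 2e-05, adjusted 1.33e-05 and 2.67e-05; −0.967 without the 2 farthest libraries, −0.848 in experiment 1 and −0.968 in experiment 2). This multi-exon component held 37.9% of the variance, against 59.2% for the component in which single-exon targets outside the receptor families stayed. Silent multi-exon targets reached up to 49.9 CPM, so DNA reads on expressed ones are not excluded, and a link to RNA amount or quality was not tested.

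The higher leukocyte markers and MHC class II genes in aged libraries may come from leukocytes among the sorted cells, although the gate for low CD45 should remove most of them. With the leukocyte term, which holds none of the MHC class II genes, the median of that list went from 1.94 to 0.11, and 3 of its 12 genes reached 5 CPM in every library, so LSECs may express part of it. The scores of both, centred within age and experiment, had r = 0.979 and rho = 0.969 (permutation p = 1e-05 for each, the smallest possible, adjusted 1.33e-05 and 2.67e-05). The r was 0.967 without the 2 farthest libraries, and 0.99 and 0.977 in experiments 1 and 2. Ptprc, which encodes CD45, was at 1.29 to 94.2 CPM, scaled without TMM. Without aged 1.3 the medians were 1.11 for MHC class II and 1.21 for Kupffer markers (larger camera adjusted p = 7.43e-06, although with all libraries the adjusted p with an estimated correlation was 0.26 and 0.147), and 0 members of either list passed over the list alone, against 7 of each. Aged 1.3 as the sole source is argued against for the Kupffer score, where the difference without it was 1.16 against an SD of 0.795 (exact permutation p = 0.0271, not adjusted). That holds only if aged 1.1 and aged 1.2, the aged libraries then left in experiment 1, are separate, and they may come from 1 pool. For MHC class II, aged 1.3 as the sole source stays open (0.777 against 1.12, exact permutation p = 0.209). Whether more leukocytes lay in aged livers or passed the sort was not tested.

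The lower early response and interferon genes in aged libraries were weighed against uneven handling, unrelated to age, and against a shared stress response. For the early response score the difference of −0.729 lay under the SD of 0.858 within groups (exact permutation p = 0.127), so uneven handling remains a candidate explanation for that list. The interferon score differed by more than its SD within groups (exact permutation p = 0.00571), but not after adjustment over the lists (0.206), and the list's adjusted p = 0.147 with an estimated correlation. A shared response cannot be told apart from separate ones, since both scores, centred within age and experiment, had r = 0.505 (permutation p = 0.064, the same after adjustment over 4 relations) and rho = 0.363 (permutation p = 0.2, likewise) but r = −0.038 without the 2 farthest libraries, −0.735 in experiment 1 and 0.766 in experiment 2. An effect of age on either list stays open.

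Other splits of the libraries within experiments show which results chance regrouping can give. Chance regrouping is argued against for the count of 23 genes over both experiments. Of 100 splits 1, the real one, gave as many, and the highest other gave 0. The splits concern the count and not each gene. They took the 2 aged libraries that may come from 1 pool as separate. No splits were run with these summed, so for that setting chance was not tested. With the receptor term 2 of 100 splits gave at least 59, and with sample weights 2 of 100 gave at least 369. Such counts are rare among the splits, but regrouping can give more, 197 and 2516, which points to a structure of the samples. The split with 197 calls was also the one with the highest other list count, 23, and agreement, 0.521. It set the libraries with the highest leukocyte term in each experiment against the others. That term was 2.37 to 5.66 against 1.55 to 1.76 in experiment 1. In experiment 2 it was 3.21 to 4.64 against 0.944 to 2.57. Whether leukocytes gave these results was not tested. Chance cannot be excluded for the 1 gene in experiment 2 (5 of 35 splits, highest other 3777), the 15 gene lists (39 of 100, highest other 23) or the agreement of r = 0.341 (9 of 100, highest other 0.521). In experiment 1 the 10 splits are too few for a share under 0.05, and the real count and the highest other were both 0, so 10 of 10 gave as many. The difference test called 0 genes, a count that 100 of 100 splits reach by necessity (highest other 3130), so its splits decide nothing. In experiment 2, 3 splits called 2445, 3459 and 3777 genes, which points to a structure of the samples. Their sides differed by 1.93, 2.31 and 2.6 in mean log2 receptor reads, against 0.57 for the split by age, but splits that differed by 2.01 and 1.9 called 0 genes, so what sets that structure is not settled. With the receptor term the age contrast of experiment 2 gave 21 genes.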
